A study of Mus musculus with 4 samples.

How the data were processed

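The study used mammalian native elongating transcript sequencing (mNET-seq), in which chromatin is digested with micrococcal nuclease, RNA polymerase II (Pol II) is immunoprecipitated and the short RNA held in its complex is sequenced. The samples were mouse B16F10 cells, an established melanoma line, either parental (control) or lacking Carm1, the coactivator-associated arginine methyltransferase that places asymmetric dimethyl marks on proteins (Carm1 KO). From each kind of cell 1 library was made with an antibody against the Pol II carboxy-terminal domain phosphorylated at serine 2 (Ser2P), a mark of elongating polymerase. Another was made with an antibody against the domain itself (clone 8WG16), titled Pol II and called total Pol II here. Whether this antibody captures all forms of Pol II alike was not checked. Per the labels' protocols, 3 sets of cells per condition were handled apart and pooled after the nuclease step, so each of the 4 libraries stands alone and no spread between replicates can be measured.

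The deposited data used here are 2 tables made by the authors, 1 for transcription start sites (TSS) and 1 for transcription end sites (TES). Each lists genes with a value for control, a value for Carm1 KO and the difference between both. The value columns name the cells and the Ser2 signal but no sample, and were assigned to the control and Carm1 KO groups by those names. The file headers call the values Ser2 fractions, but they reach 35.98 in control and 38.92 in Carm1 KO at the TES, so they were treated as a linear ratio in which the authors set the Ser2P signal against another signal, per the file headers. The divisor is not stated in the sources used here; the total Pol II library of the same cells is the series' only other library of each kind of cell. The width of the windows, the scaling between libraries, the strand setting of the counting and the rule by which the authors chose the genes are not given in the sources used here either. The tools cutadapt 1.18 and TopHat2 2.1.1 and the builds mm10 and GRCm38 are named, with no settings, per the submitters' processing notes. The deposited difference equalled Carm1 KO minus control within 1e-09 in every one of the 3112 TSS genes and 3030 TES genes, and was not used further. The tables hold no columns of other samples.

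Depth is unknown, because neither table gives read counts, and no counting interval was computed. The values are coarse: of the genes above 0 at the TSS, 1183 in control and 1599 in Carm1 KO had exactly the value of another gene, and at the TES 672 and 754 did. Genes listed at 0 were 101 in control and 194 in Carm1 KO at the TSS, and 11 and 7 at the TES. No fold was computed for them, which left 2859 genes at the TSS and 3016 at the TES.

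For the remaining genes the change was log2(Carm1 KO / control) with no pseudocount. A gene was called higher or lower when it passed 1.5-fold (0.58 on the log2 scale). With 1 library per group no test of the conditions was run, no p-value is given, and each call describes these libraries only. Both tables share the same libraries, so a factor that applies to a whole library moves TSS and TES values together. The median of all genes was therefore also subtracted, and gene groups are given relative to it.

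A total of 21 gene lists were fixed before the data were examined, as were the design, the size threshold and the alternatives. For each list with at least 5 compared genes, the median change was placed among 10000 random lists of the same size, matched on deciles of the mean of the control and Carm1 KO ratios. A list at or below percentile 2.5 or at or above percentile 97.5 was called apart from random lists. This percentile describes the libraries and is not a p-value over replicates, since genes are not replicates. Of 36 placements 1.8 would fall outside these limits by chance alone. Tested on simulated data with 200 lists of 25 genes per setting, the procedure called 5.5% of unshifted lists at each end. At the TES it called 72.5% of lists raised by 0.5 and 63% of lists lowered by 0.5 on the log2 scale. At the TSS it called 38% and 40.5% of such lists, and 92.5% and 92% of lists moved by 1. The simulated changes were independent of level and gene length, and list members were drawn at random. These rates therefore need not hold for the real lists.

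Named genes followed a rule fixed in advance. It takes the arginine methyltransferase genes, the 10 genes with the largest change each way at each end among symbols that are not predicted or small RNA genes, the 2 members of each list with the largest change each way at each end, and genes passing the threshold at both ends (up to 10 for each shared direction and up to 5 for each opposite direction). Genes named outside this rule are pointed out. Some genes that the rule names are not reported here. Symbols in the tables are in capitals. They were matched without regard to case to GENCODE M21 on GRCm38, the build the processing notes name, giving 1 gene model for 3066 TSS genes and 2985 TES genes. For 6 symbols in each table more than 1 model matched, and no coordinates were taken. Coordinates are 1-based, and lengths are those of the gene models. Histone and ribosomal protein genes have near-identical copies, and overlapping genes can share reads, so their values are less certain.

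Alternatives changed the threshold (1.25-fold and 2-fold), the genes (genes above the median of mean level, no predicted or small RNA genes), the pseudocount (10th percentile of values above 0) and the centring, and for lists the matching and the summary. Splits by gene length, matching on gene length and a limit on the control TSS ratio of 0.3 were added after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.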

Results

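The data covered 4 mNET-seq libraries of B16F10 mouse melanoma cells, 1 each for Ser2P and total Pol II in control and Carm1 KO cells. For each gene the deposited tables gave the Ser2P ratio in control and in Carm1 KO cells, at the TSS for 3112 genes and at the TES for 3030 genes, with 3025 genes in both tables. The ratio sets Ser2P signal against another signal that the sources used here do not name. The signals are not given apart, so a change of the ratio may lie in the Ser2P signal or in the divisor. Read depth per library was unknown. With 1 pooled library per group, no difference could be set against a spread between replicates, and the values below describe these libraries. Carm1 itself was not analysed here, so the knockout could not be checked from its own value. The direction of every change rests on the names of the table columns, which were read as control and Carm1 KO.

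In control cells the Ser2P ratio was low at gene starts and high at gene ends. Its median over all listed genes was 0.0809 at the TSS, with quartiles at 0.0422 and 0.157, and 1.71 at the TES, with quartiles at 1.07 and 3.21. Of the 2775 genes above 0 in both conditions at both ends, 2692 had a higher ratio at the TES than at the TSS in control cells and 2604 did in Carm1 KO cells. The median gene had a TES ratio 19.5 times its TSS ratio in control cells and 15.7 times in Carm1 KO cells.

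The first comparison asked how loss of Carm1 altered the Ser2P ratio at the TSS. The ratio was higher in Carm1 KO cells for most genes. The median change was 1.17 on the log2 scale, or 2.25-fold, with quartiles at 0.46 and 1.89, and 2452 of 2859 genes (85.8%) were higher. At least 1.5-fold, 2036 genes were higher and 160 were lower. The direction of this majority depends on the scale between libraries, which is not given. After the median of all genes was subtracted, 819 genes were higher and 823 lower by that factor. Subtracting the median puts equal numbers of genes on each side of 0 by construction. The centred counts therefore cannot tell a difference in scale from a rise at most genes. A difference in scale may account for the majority by itself. The most frequent single ratio above 0 was 1.03 in control and 2.68 in Carm1 KO cells at the TES, and 0.0857 and 0.168 at the TSS. Such coarse values need not mark the same step in both libraries, so they do not measure a difference in scale. Whether scale or genotype sets the majority was not tested. Among genes listed at 0 in 1 condition only, 59 were at 0 in control and 152 in Carm1 KO.

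Of the arginine methyltransferase genes, 5 were listed at the TSS and each was at least 1.5-fold higher in Carm1 KO cells. Prmt7 changed from a ratio of 0.0876 to 0.526 (log2 change 2.59), Prmt6 from 0.0618 to 0.361 (2.55) and Prmt5, the main enzyme of symmetric arginine dimethylation, from 0.0279 to 0.149 (2.42). Prmt1, the main enzyme of asymmetric dimethylation, changed by 1.72 and Prmt3 from 0.190 to 0.430, the latter close to the median of all genes. All 5 lay above that median. The median of the 5 genes lay at percentile 97.4 of random lists matched on level, inside the limit for a list called apart, and at percentile 98.3, outside it, when matched on gene length.

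Leaving out predicted and small RNA genes, the TSS ratio of Abhd5, a coactivator of triglyceride lipase, was among those with the largest increases, with a log2 change of 6.20. Lrba changed by 5.61, the antisense gene Bloc1s6os by 5.34, the Pol III subunit gene Polr3g by 5.28 and the exocyst gene Exoc3 by 5.16. Trappc4 changed by 4.76, the small Maf factor gene Mafg by 4.74 and Tial1 by 4.63. Several of these changes start from control ratios far below the median of all genes, such as 0.00382 at Abhd5. Among the largest decreases were those at Max (log2 change -3.39), the partner of Myc, Flvcr1 (-3.12), the ribosome biogenesis GTPase gene Gtpbp4 (-3.09), Tnpo3 (-2.77), which encodes an import receptor for splicing factors, and the small RNA host Zfas1 (-2.52). Trappc2l (from 0.245 to 0.0433), Kin (-2.46), Paip2b (-2.45), Xpnpep3 (-2.31) and Mllt11 (-2.26) followed. Max had a TSS ratio of 0.0989 in control and 0.00945 in Carm1 KO cells. All of these decreases end at Carm1 KO ratios below the lower quartile of all listed genes, 0.0837. At the TSS, 1183 control and 1599 Carm1 KO values are shared with another gene. The largest changes at the TSS, in both directions, are therefore uncertain for single genes.

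**Figure D1:**
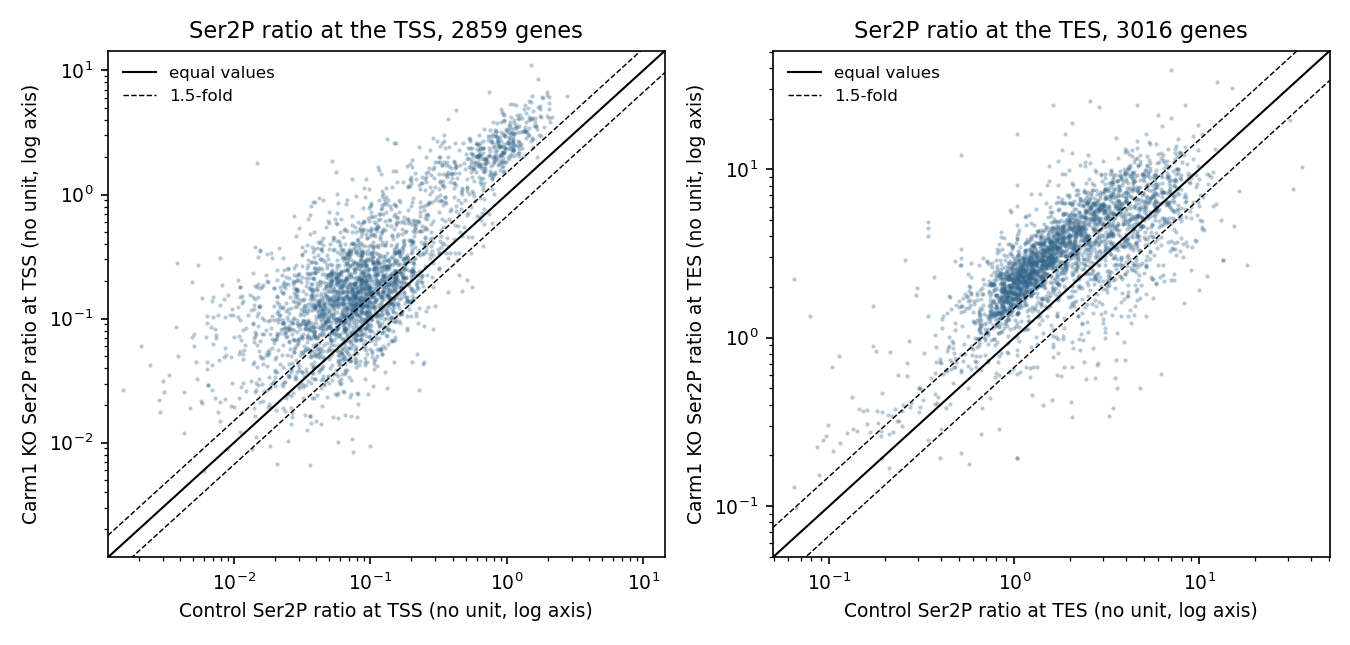
Ser2P ratio of each gene in control (x axis, log scale) against Carm1 KO cells (y axis, log scale) at the TSS (left, 2859 genes) and the TES (right, 3016 genes); each point is 1 gene, the solid line marks equal values and the dashed lines 1.5-fold. Most points lie above the line of equal values, 2452 at the TSS and 2541 at the TES.

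Of 18 gene lists large enough to place at the TSS, 3 stood apart from random lists of the same level. List medians are given as deposited, and those under 1.17 at the TSS or 0.85 at the TES fall below 0 once the median of all genes is subtracted. Host genes of small RNAs and abundant noncoding RNAs had a median of -0.02 over 14 genes, which is 1.19 below that of all genes, at percentile 0.01. In this list 7 genes lay above 0. By the threshold 6 genes were at least 1.5-fold higher, 2 lower and 6 in between. The list holds Rmrp and Rpph1 (-0.40), which Pol III transcribes, and its median without them was not computed. Snhg6 (1.75) and Snhg3 (1.54) lay at the upper end, while Snhg4 (-1.24) and Rmrp (-0.81), the RNA component of a mitochondrial RNA processing endonuclease, lay at the lower end. Replication-dependent histone genes were higher by less than other genes, with a median of 0.63 over 34 genes, 0.54 below that of all genes, at percentile 1.46. Of these 17 were at least 1.5-fold higher and 0 lower, and the extremes were Hist1h2ag (3.41), Hist1h2bf (1.91), Hist1h3a (-0.23) and Hist1h4h (-0.41). With the mean of the TSS and TES changes the small RNA hosts were at percentile 3.29 and the histones at 25.6, inside the limits. Hist1h2ag, Hist1h2bf, Snhg3 and Zfas1 have the annotated end of another gene within 1 kb of their TSS.

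The third list, genes for cleavage, polyadenylation and termination of transcripts, was higher than random lists, with a median of 1.85 over 15 genes, 0.69 above that of all genes, at percentile 99.2. Of its genes 11 were higher and 1 was lower. Nudt21 (3.03), a subunit of cleavage factor I, and Pcf11 (2.56), a termination factor, led the list, and Wdr82 (-0.38) and Cpsf2 (-0.82) were at its lower end. The call did not hold when random lists were matched on gene length (percentile 94.9) or when the share of genes above the median of all genes was used (93.9), and with the mean of both ends the list lay on the low side, at percentile 7.04.

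The other 15 lists stayed inside the limits at the TSS. Oxidative phosphorylation genes had a median of 1.70 over 24 genes, with 18 higher and 1 lower, at percentile 93.7. Their extremes were the complex I genes Ndufa5 (from 0.00797 to 0.128) and Ndufb10 (3.64), and Ndufa10 (-0.45) and the cytochrome oxidase gene Cox6c (-1.48). With matching on gene length the list was at percentile 99.2 and with the mean of both ends at 99.8. Ribosomal protein genes had a median of 0.78 over 69 genes, with 39 higher and 3 lower, at percentile 3.19 on matching by level and 1.11 on matching by length. Rpl13 (3.58) and Rpl23a (2.49) were at the upper end and Rps26 (-1.06) and Rps20 (-1.26) at the lower end. Rpl13, Rpl23a and Rps20 have another gene's end within 1 kb of the TSS. Immediate early genes had a median of 0.51 over 24 genes, with 11 higher and 4 lower, at percentile 6.05 by level and 1.2 by length. Zfp36l1 (2.59), which also has a gene end near its TSS, and the nuclear receptor gene Nr4a2 (2.20) contrasted with Klf10 (-1.19) and the phosphatase gene Dusp2 (-1.31). Melanocyte and pigment genes had a median of 0.55 over 13 genes, with 5 higher and 0 lower, at percentile 3.68. Here Mc1r, the melanocortin receptor gene, changed by 3.32, with another gene's end near its TSS, and Myo5a by 1.99, whereas the melanin synthesis genes Tyrp1 and Tyr had log2 changes of -0.21 and -0.24.

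Among the remaining lists at the TSS, reported Carm1 substrates and partners had a median of 1.66 over 10 genes, with 8 higher and 0 lower (percentile 90.6). Ep300, a histone acetyltransferase gene, changed by 1.99, Sf3b4 by 0.54 and Pkm by 0.47. Ep300 and Sf3b4 have another gene's end near the TSS. p53 targets had a median of 1.35 over 9 genes (percentile 81.8), between Trp53inp1 (2.55), Gadd45b (2.22), Btg2 (-0.02) and Ccng1 (-0.10). DNA damage response genes had a median of 1.14 over 25 genes, with 18 higher and 2 lower (percentile 48.6). The mismatch repair gene Msh6 changed by 4.28 and Brca2, of homologous recombination, by 3.06. At the lower end were Parp2 (-0.70) and Xpc, whose ratio fell from 0.113 to 0.0497. Parp2 has another gene's end near its TSS, that of Rpph1 on the opposite strand. Cell cycle and replication genes had a median of 1.06 over 34 genes, with 22 higher and 3 lower (percentile 34.9), from Mki67 (ratio 0.0219 in control, 0.124 in Carm1 KO) and Mcm5 (2.43) to Orc1 (-0.82) and Cdc20 (-1.95). Pol II elongation and pausing factors had a median of 0.92 over 18 genes, 13 higher and 0 lower (percentile 23.6), with Rpap2 (3.87) and Polr2d (3.19) at the upper end and Tcea1 (0.11) and Ctdp1 (0.01) at the lower end. Splicing factor genes had a median of 1.13 over 41 genes, 30 higher and 1 lower (percentile 66.7), from Sf1 (2.66) and Snrpe (2.39) to Sf3b3 (-0.21) and Rbm39 (-0.82). Myc targets and ribosome biogenesis genes had a median of 0.77 over 25 genes (percentile 9.45), heat shock and unfolded protein response genes 0.65 over 17 (percentile 17.3), chromatin regulators 1.21 over 12 (percentile 44.3) and antigen presentation genes 1.00 over 5 (percentile 47.8). In the last list Calr changed by 2.06 and Tapbp, with another gene's end near its TSS, by 1.47, while B2m, the light chain of class I molecules, had a log2 change of -1.14.

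The second comparison asked the same of the TES. The Ser2P ratio was again higher in Carm1 KO cells for most genes, with a median change of 0.85 on the log2 scale, or 1.80-fold, and quartiles at 0.35 and 1.17. Of 3016 genes, 2541 (84.3%) were higher. At least 1.5-fold, 2013 were higher and 215 lower, and after the median of all genes was subtracted 349 were higher and 664 lower. The majority at the TES depends on the scale between libraries too, and the centred counts cannot decide between scale and a rise there either. The change varied with gene length. With genes in 10 groups of equal number by length, in the shortest group, up to 3170 bp, the median change was 0.86 and 11 of 298 genes were lower in Carm1 KO cells, whereas in the longest group, from 77497 bp, it was -0.09 and 162 of 297 genes were lower. Over the 6 shorter groups, up to 24989 bp, the median was 0.86, 0.89, 1.00, 1.04, 1.00 and 1.01. In the 4 longer groups it was 0.85, 0.67, 0.21 and -0.09. At the TSS the medians lay between 1.03, in the shortest group, and 1.34, in group 8, with 1.13 in the longest.

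**Figure D2:**
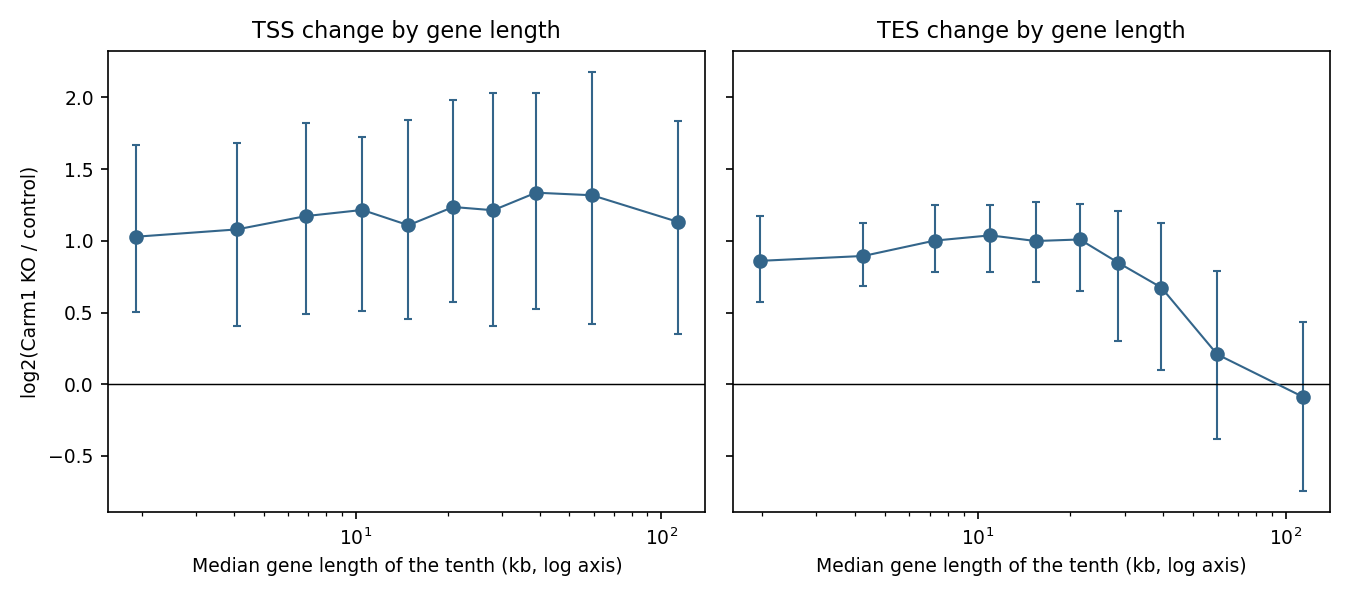
Change of the Ser2P ratio, log2(Carm1 KO / control), at the TSS (left) and TES (right) in 10 groups of genes by annotated length (x axis, median length in kb, log scale); points are medians over genes and bars interquartile ranges. At the TES the median change lies between 0.86 and 1.04 in the 6 shorter groups and then falls to -0.09 in the longest, while at the TSS it lies between 1.03 and 1.34 in all 10 groups.

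Leaving out predicted and small RNA genes, the largest TES increases were at Mst1 (log2 change 4.55), which encodes a hepatocyte growth factor-like protein, Styxl1 (4.09), Rnf32 (3.97), the monocarboxylate transporter gene Slc16a6 (3.90) and H2-DMa (3.82), a chaperone of class II antigen presentation. The autophagy enzyme gene Atg7 (3.71), the readthrough gene EEF1AKMT4-ECE2 (3.55), Tmco4 (3.31), the mitochondrial glutamyl-tRNA synthetase gene Ears2 (3.19) and Cdnf (3.10) followed. Slc16a6 had a TES ratio of 1.62 in control and 24.2 in Carm1 KO cells. The largest decreases were at Nsmce2 (-3.35), a SUMO ligase of the SMC5/6 complex, Eipr1 (-3.25), the mitochondrial leucyl-tRNA synthetase gene Lars2 (-3.25), Vps13b (-3.16), Sclt1 (-2.84) and the circadian repressor gene Cry1 (-2.74). Tmem116 (-2.62), Pfn4 (-2.60), Rnf13 (-2.43) and Ccdc138 (-2.42) followed. Cry1, which spans 85131700 to 85185064 on the minus strand of chromosome 10 (GRCm38), had a TES ratio of 18.0 in control and 2.68 in Carm1 KO cells. The control ratio of Rnf32, 1.03, was shared by 28 genes and the Carm1 KO ratio of Cry1 by 24, so such values are coarse. H2-DMa, Atg7 and EEF1AKMT4-ECE2 had the same control ratio, 0.343, and Slc16a6 and Ercc6 the same Carm1 KO ratio, 24.2. Ccdc138 and Mipol1 shared both ratios, 1.03 in control and 0.192 in Carm1 KO cells. The largest changes therefore include many coarse values and are uncertain for single genes.

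None of the 18 lists placed at the TES passed the percentile limits. Arginine methyltransferase genes had a median of 1.16 over 5 genes (percentile 88.0), with Prmt6 at 1.73, Prmt5 at 1.39, Prmt1 at 1.16, Prmt7 at 0.16 and Prmt3 at -0.61. Ribosomal protein genes were higher at the TES in 62 of 62 cases, 51 of them at least 1.5-fold, with a median of 0.80 and a range from 0.26 at Rpl41 and 0.33 at Rps27 to 1.09 at Rps15a and 1.20 at Rpl36a (percentile 56.6). Against the median of all genes, 21 lay above and 41 below. Histone genes had a median of 0.71 over 31 genes, 18 higher and 0 lower (percentile 56.7), between Hist1h4b (1.62), Hist1h4c (1.43), Hist2h2be (0.21) and Hist1h2bh (0.00). Their median control ratio was 0.21, against 1.71 for all genes. Myc targets and ribosome biogenesis genes had a median of 1.05 over 26 genes, 23 higher and 0 lower (percentile 88.8). Tfrc, the transferrin receptor gene, changed by 1.41 and Gnl3 by 1.36, while Fbl changed by 0.43 and the Pol I subunit gene Polr1a by -0.18. In this list 21 genes lay above the median of all genes and 5 below, a share at percentile 99.3.

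DNA damage response genes at the TES had a median of 0.73 over 25 genes, with 17 higher and 1 lower (percentile 27.9). Ercc6, of transcription-coupled repair, changed from a ratio of 4.59 to 24.2 (2.39) and Xrcc3 by 1.64. Blm, a helicase gene, changed by 0.04, and Prkdc, the catalytic subunit of DNA-dependent protein kinase, changed from 9.94 to 1.92 (-2.37). Genes for cleavage, polyadenylation and termination had a median of 0.60 over 15 genes, 8 higher and 3 lower (percentile 13.9), from Cstf1 (1.27) and Wdr82 (1.12) to Cstf3 (-1.48) and Scaf8 (-1.73). Elongation and pausing factors had a median of 0.67 over 18 genes, 10 higher and 2 lower (percentile 15.8), with Larp7 (2.11) and Ell (1.45) at the upper end and the phosphatase gene Ctdp1 (-0.62) and the P-TEFb cyclin gene Ccnt2 (-1.22) at the lower end. Melanocyte and pigment genes had a median of 0.70 over 11 genes, 6 higher and 1 lower (percentile 26.2), between Slc24a5 (1.46), Mlph (from 1.73 to 4.11), the receptor kinase gene Met (-0.44) and Rab38 (-0.76). Cell cycle and replication genes had a median of 0.89 over 32 genes, 26 higher and 0 lower (percentile 45.7), with Ccne2 (1.60) and Mcm7 (1.29) above and E2f3 (-0.41) and Pola1 (-0.46) below. Splicing factors had a median of 0.93 over 39 genes, 31 higher and 1 lower (percentile 61.1), with values such as those of Prpf31 (from 0.722 to 2.04), Sf3a2 (1.45) and Snrnp70 (-0.38). The medians of the other lists were 0.84 for Carm1 substrates and partners (11 genes, percentile 64.0), 0.95 for antigen presentation (5 genes, 65.9), 0.92 for p53 targets (9 genes, 72.5), 0.80 for immediate early genes (24 genes, 49.8), 0.87 for heat shock and unfolded protein response (16 genes, 47.3), 0.90 for oxidative phosphorylation (24 genes, 55.1), 0.84 for chromatin regulators (13 genes, 67.5) and 0.66 for small RNA hosts (10 genes, 27.0).

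**Figure D3:**
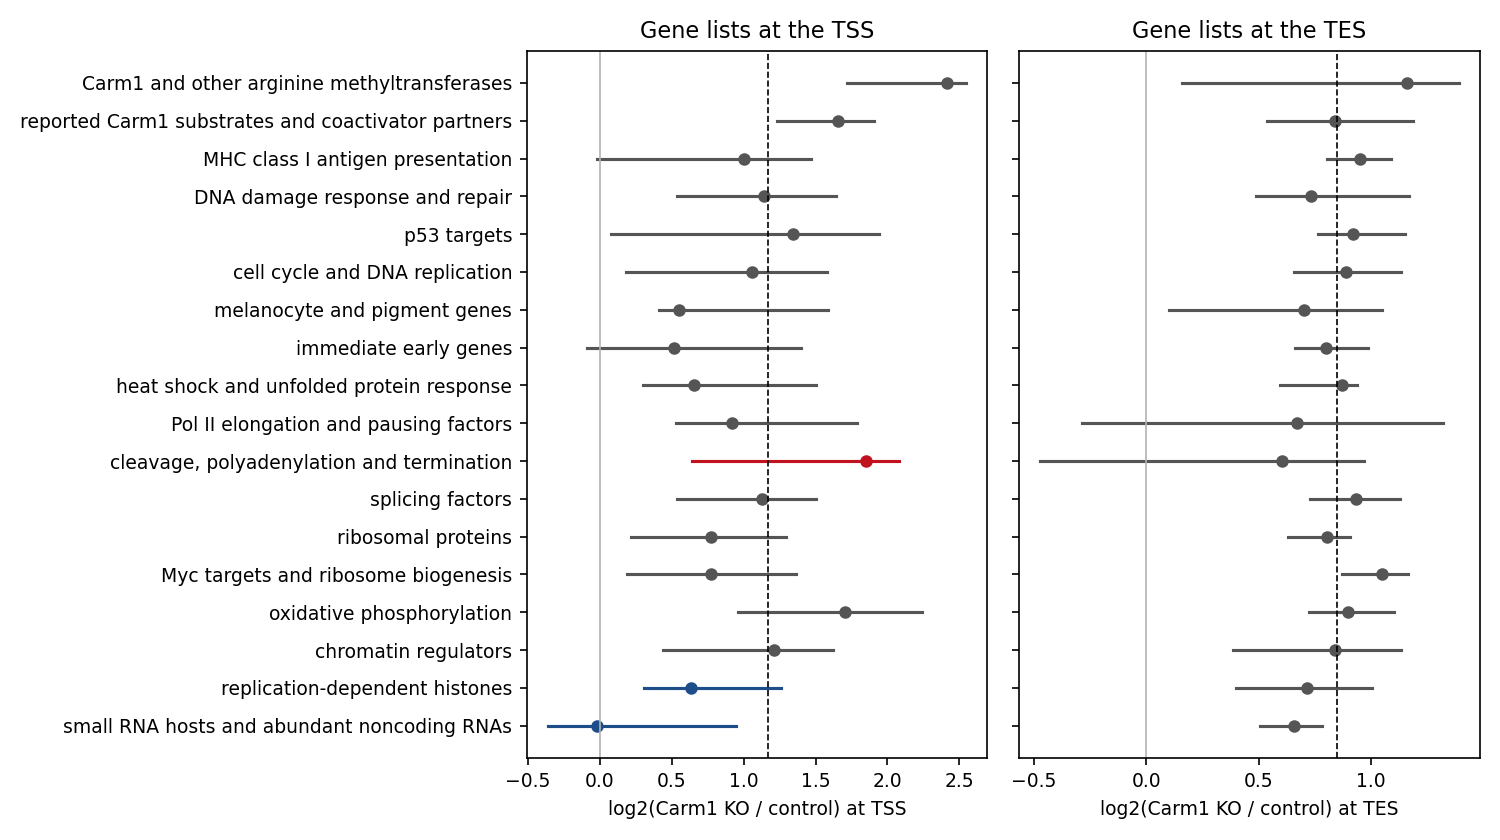
Change of the Ser2P ratio, log2(Carm1 KO / control), in each gene list at the TSS (left) and TES (right); points are list medians, bars interquartile ranges over genes, the dashed line the median of all genes (1.17 at the TSS, 0.85 at the TES) and the grey line 0. Lists beyond the percentile limits are red (higher, cleavage and polyadenylation at the TSS) or blue (lower, histones and small RNA hosts at the TSS), and grey points lie inside the limits.

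Lists with fewer than 5 compared genes give values only. Of the interferon response list, 3 genes were compared at the TSS and 4 at the TES. Ifit2 had a ratio of 0.0935 in control and 0.0839 in Carm1 KO cells at the TSS (-0.16) and a change of -0.22 at the TES. Dhx58 changed by 1.22 and 1.16, Zc3hav1 by -0.27 and 1.47, and Adar by 0.78 at the TES. Of the cytosolic DNA sensing list, Trex1, the exonuclease that removes cytosolic DNA, changed by 1.59 at the TSS and 1.69 at the TES, G3bp1 by -0.61 and -0.69, and Mre11a by 0.45 at the TES. These genes were named because their lists were short, outside the rule for named genes. Of the immune and stromal cell markers only Cd68 was compared, and it changed by 0.80 at the TSS and 0.88 at the TES.

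The last comparison set the change at the TSS against that at the TES in the 2775 genes compared at both ends. Across genes, which are not independent replicates, the changes had a Spearman rho of 0.02 and a Pearson r of -0.0005. At least 1.5-fold, 1365 genes were higher at both ends, where independent lists would share 1330, and 17 were lower at both, where 11.1 would be. In opposite directions, 127 were higher at the TSS and lower at the TES, with 141 from independent lists, and 95 were lower at the TSS and higher at the TES, with 105. These comparisons depend on the scale between libraries. After the median of all genes was subtracted, 90 genes were higher at both ends, with 90.5 from independent lists, and 199 lower at both, with 173. On that scale 200 were higher at the TSS and lower at the TES, with 174, and 83 the opposite, with 89.6. The ratio of TES to TSS values was lower in Carm1 KO cells for 1759 genes (63.4%), with a median log2 change of -0.40. This quantity does not depend on a factor common to a whole library.

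Genes higher at both ends were led by Slc16a6 (2.73 at the TSS and 3.90 at the TES), Rgs2, a regulator of G-protein signalling (3.08 and 2.61), 5031434O11Rik (4.04 and 2.54), Pccb, a subunit of propionyl-CoA carboxylase (2.53 and 2.48), and the lysosomal sulfatase gene Galns (2.67 and 2.41). Dbt (2.57 and 2.19), Nsun4 (2.25 and 2.16), H2-DMa (TSS ratio from 0.253 to 1.08, TES change 3.82), Cryz (2.21 and 2.02) and the Integrator subunit gene Ints2 (TSS change 2.05, TES ratio from 1.73 to 6.89) followed. Genes lower at both ends were led by Fbxl12os (-1.64 and -1.52), which has another gene's end within 1 kb of its TSS, the microtubule-binding protein gene Clasp1 (-1.23 and -1.29), Rnf13 (-1.23 and -2.43), Arid4a (-1.11 and -1.13) and Mipol1 (-1.10 and -2.42). Sltm (-0.76 and -0.81), 2610035D17Rik (-0.72 and -0.89), the Fanconi anaemia ligase gene Fancl (-0.89 and -0.71) and the casein kinase 2 gene Csnk2a1 (-1.18 and -0.71) were also lower at both. Rmrp (-0.81 and -0.81) passed the threshold at both ends too, but its control ratios of 0.673 at the TSS and 0.672 at the TES are nearly equal, so its ends are not separate measurements. Vps13b (2.54 and -3.16), Lars2 (2.40 and -3.25), GM45935 (3.15 and -2.35), Sclt1 (2.27 and -2.84) and the ketone body enzyme gene Oxct1 (3.28 and -2.11) were higher at the TSS and lower at the TES. Mttp (-1.75 and 2.32), Hyls1 (-2.09 and 1.53), Ears2 (-1.45 and 3.19) and Sertad1 (-1.41 and 1.45) were lower at the TSS and higher at the TES.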

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

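No replicate could be left out and no paired analysis was possible because each group has 1 library; read depth is unknown, so the precision of single genes cannot be given. Each gene symbol stood once in each table, so averaging repeated symbols was not run. The splits by gene length, matching on length and the limit on the control TSS ratio were chosen after seeing the data. The median change stayed above 0 in every alternative except centring, which sets it to 0 by construction. For gene length this holds for the split at 30 kb only, since the TES median was -0.09 in the longest of 10 length groups. At the TSS the median was 1.43 in genes above the median level (93.0% of genes higher, 1164 at least 1.5-fold higher and 26 lower) and 0.87 with a pseudocount (81.8% higher). It was 1.22 in genes over 30 kb (650 higher, 59 lower) and 1.07 with a control ratio of at most 0.3 (83.9% higher), and genes of at most 30 kb had 97 lower. Centring left 49.98% of TSS genes higher, 819 by 1.5-fold and 823 lower, and a 2-fold threshold left 83 lower. At the TES the median was 0.74 in genes above the median level (78.5% higher, 883 and 134 past the threshold) and 0.57 with a pseudocount. It was 0.96 in genes of at most 30 kb (94.7% higher, 30 lower) and 0.30 in genes over 30 kb (63.5% higher, 391 past the threshold). Centring left 50% of TES genes higher, 349 by 1.5-fold and 664 lower, and a 2-fold threshold left 1143 higher and 121 lower. The 2-fold threshold gives smaller counts by construction. Subsets of genes hold fewer genes, but their shares of higher and lower genes also differ from those of all genes, and the cause of these shifts was not tested. The correlation of TSS with TES changes was -0.033 in genes above the median level. Lists beyond the percentile limits numbered 3 with matching on level, 7 without matching, 5 for the share above the median and 5 with matching on length; with the mean of both ends there were 2, the oxidative phosphorylation list counted at each end (99.8). The cleavage and polyadenylation list turned to percentile 7.04 with the mean of both ends, the small RNA host list was then at 3.29 and the histone list at 25.6; the cause was not tested. Without matching, the arginine methyltransferase list (97.9), immediate early genes (0.57), ribosomal proteins (0.585) and oxidative phosphorylation (98.2) also passed at the TSS. For the small RNA hosts matching on length was not possible, since under 80% of the list had a gene model. Among genes named by the rule, centring turned 2 called values, B2m at the TES (-0.044) and Tapbp at the TES (-0.21), below 0. It took 27 below the threshold and 21 past it with the same sign. A further 14 went from a rise below the threshold to a fall past it, such as Prmt7 at the TES (0.16 to -0.69). The pseudocount took 20 below the threshold and turned none. Of genes named outside the rule, centring also turned Terc (-0.35 at the TSS, -0.12 at the TES), Adar at the TES (-0.07) and Cd68 at the TSS (-0.36).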

Other observations

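The tests of the longest against the shortest genes with unshared values and of single libraries were chosen only after the result was seen, and the patterns themselves were noticed in these data before any test of them. Intervals are 95% bootstrap intervals over genes, which are not replicates.

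Rmrp and Rpph1, which Pol III transcribes, had lower values in Carm1 KO cells. Rmrp had a ratio of 0.673 in control and 0.384 in Carm1 KO cells at the TSS (log2 change -0.81) and Rpph1, the RNA of ribonuclease P, 0.775 and 0.588 (-0.40). At the TES their changes were -0.81 and -0.42, but the ratios are nearly the same numbers as at the TSS, so both ends do not count as separate measurements. Terc, the telomerase RNA and a Pol II transcript, changed by 0.81 at the TSS and 0.73 at the TES as deposited, but lay below the median of all genes at both ends, by -0.35 and -0.12, so its sign turns when that median is subtracted. These 3 genes were singled out after their values were seen.

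The TES change had a Spearman rho of -0.34 with length across genes, with the lowest medians in the longest of 10 length groups and no test of the trend within shorter genes alone: the control ratio had a rho of 0.79 with length, from a median of 0.778 in the shortest group to 4.64 in the longest, and the Carm1 KO ratio a rho of 0.58, from 1.40 to 4.39. Within deciles of TES level the mean rho was -0.276 (-0.31 to -0.24), and single deciles ran from -0.488 to -0.030. This argues against a dependence on level alone only in part, since level still varies within a decile and length tracks it. Signal from neighbouring genes is argued against by a rho of -0.396 (-0.44 to -0.35) in 1607 genes with no other gene within 2 kb. A lower ratio over whole long genes is argued against by a TSS rho of 0.0529 (0.014 to 0.089). Coarse values of weakly covered genes may contribute, as rho was -0.227 (-0.28 to -0.18) in the 1866 genes with unshared values. They are argued against as the whole cause, since there the longest group differed from the shortest by -0.75 (-0.99 to -0.54). A candidate explanation is that loss of Carm1 lowers the Ser2P ratio at the ends of long genes relative to short ones. With 1 library per group this cannot be told apart from a property of the single libraries. A change in the Ser2P signal cannot be told apart from a change in the divisor either.

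Genes with a high TSS ratio in control were compared with the rest by annotation, as the 563 genes with the highest control ratio, 20% of those compared with a gene model. Another start site over 1 kb downstream was annotated for 13.1% of these genes and 15.6% of the rest, a difference of -2.44 points (-5.58 to 0.68). Annotated sites of this kind therefore cannot account for most of the high ratios. Annotation does not show which start site is in use in these cells, so sites that are not annotated were not tested. The end of another gene lay within 1 kb of the TSS for 31.3% of them and 9.14% of the rest, a difference of 22.1 points (18.5 to 26.0). Signal from a neighbouring gene's end is therefore a candidate source for part of the high ratios, while most of these genes have no such neighbour annotated, and no biological explanation was tested. The shares were not split by strand, and a nearby end can lie on the opposite strand, as that of Rpph1 does at Parp2.

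The small RNA host list, whose TSS change was far below other genes, was followed into genes outside the list. Of these, 144 held a small nuclear or nucleolar RNA gene and had a median TSS change of 1.01, against 1.19 for 2661 without, a difference of -0.17 (-0.35 to 0.03). Those with the small RNA gene within 1 kb of the TSS (22 genes) differed from those with all further away (122 genes) by -0.034 (-0.38 to 0.59). A small RNA gene inside the host may account for a small part of the list's low change, but the first interval ends far short of the list's distance from all genes, -1.19, and does not exclude 0. That distance includes the Pol III transcripts Rmrp and Rpph1, and it was not computed for the host genes alone. What else sets the list apart, a genotype effect included, stays open and untested.

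At the TES the most frequent control ratio, 1.03, was shared by 28 genes and the most frequent Carm1 KO ratio, 2.68, by 24 genes.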
